A study of Homo sapiens with 7 samples.

How the data were processed

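Bulk RNA sequencing was done on 7 libraries of the human lung cancer line PC9. Per the labels, 3 were of parental cells and 4 of AXL knockout cells, from 2 clones with 2 libraries each. The design text and the sample labels name the clones differently, and the names were not matched to each other. Per the labels' protocols, RNA was reverse-transcribed from poly-T primers with sample barcodes, amplified by transcription and made into libraries by bulk MARS-seq, sequenced on a NextSeq 500, mapped to the human genome and filtered. The aligner, the counting, the use of molecular identifiers and strand, the genome build and the annotation are not given in the sources used here. DESeq2 is named per the submitters' processing notes, without a version.

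What was analysed is the authors' comparison table. Per the file headers, the authors deposited, for each Ensembl gene, a signal (the mean over the libraries of normalized counts), a log2 fold change with its standard error on the log2 scale, a score (the Wald statistic), and a p-value with its adjusted p-value. In these deposited columns the score equals the fold change divided by its standard error to within 1.56e-13, the p-value is the 2-sided normal one, and the adjusted p is the Benjamini-Hochberg value over all 16522 rows with a test. The other 5 of the 16527 rows have a mean of 0. Values per library were not analysed here. The fits planned for counts (edgeR with its alternatives), the comparisons of each clone with parental cells and of the clones with each other, the overlap between clones and the AXL level in each library were therefore not run, and the authors' DESeq2 statistics are reported in their place.

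The table does not name its contrast, and its direction was read from its lowest rows. All 68 rows with a mean above 0 and under 0.6 are sums of whole reads over 7 steps, 1 per library, to within a tolerance of 1e-10. Of these steps, 3 go with a negative and 4 with a positive fold change. In 31 of 31 rows with reads on 1 side the sign of the fold change matches that side. The sides were assigned largely from the signs of these same rows, so the match shows only that the rows do not conflict. The labels give 3 parental and 4 knockout libraries, so positive values are higher in knockout cells. The steps give size factors of 0.938 to 1.06. The level of each group was computed from the mean and the fold change, with weights of 3 and 4 libraries. On simulated data for 1962 genes these levels were off by a median of 0.00866% and at most 0.575%. Only genes with ample reads in both groups were kept there, so genes with few reads in a group were not covered. A gene was treated as near the floor when its lower group held 3 implied reads or fewer. Such genes are given by levels, of which the lower comes from the same fitted fold and marks only a group near the floor. Intervals are 95% normal intervals from the authors' standard errors. With 4 knockout libraries from 2 clones, p-values measure the spread between these libraries, part of which may be technical, and differences that arose in a single founding cell cannot be separated from the effect of the knockout.

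Symbols were matched for 16428 of the 16527 identifiers with a table of gene names, and 99 had no match. GENCODE 29 (GRCh38) held 16517 of the identifiers and gave positions, transcript lengths and GC content. These positions are those of GENCODE, since the table has no coordinates. The gene lists, the thresholds, the rule for named genes and the other settings to be tried were fixed before the data were examined. The rule took genes with an adjusted p under 0.05 and a mean of at least 20 in the higher group, and named the 12 largest rises, the 12 largest falls and up to 4 members of each list with the smallest p. Its conditions on each clone and on separation of the libraries could not be applied to this table. The 12 largest rises and falls above the floor with a mean of at least 100 in the higher group were added after the values had been seen. Some genes that the rule took are not reported here.

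The 42 lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic with a preset correlation of 0.01. Members were also counted after adjustment over the list alone, which gave the same counts as over all genes unless stated. Alternatives that could be run were a threshold of 0.01, a 2-fold minimum and a mean count of at least 20. Those added after the data were seen were a t distribution with 5 degrees of freedom, a test against an absolute log2 fold change of 0.5, centring, and for the lists a correlation of 0.05, ranks, the log2 fold change itself, 10000 random lists matched on mean count, and the removal of AXL or of genes in regional runs. Regional runs were sought over 10404 nuclear protein-coding genes with a mean of at least 50, in windows of 21 genes against 1000 permuted gene orders, on fold changes centred on their median of 0.01. Bootstrap intervals are 95% intervals of a median.

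The steps were tested on simulated data. In a table of 16522 simulated genes with 200 changed, the share recovered for the comparison of AXL knockout with parental was 68% at a log2 fold change of 0.5, 94% at 1, 96% at 2 and 100% at 3, and 5.79% of the calls were unchanged genes. The noise was drawn from the authors' standard errors without any difference between clones, so these shares are not error rates of the real calls. In 50 simulated tables the set test found the shifted list in 50, and it called 0 of 2050 unshifted lists. The simulated statistics were independent between genes, so this does not show how often lists of genes that move together are called wrongly. In the scan, a block of 40 genes shifted by -0.8 was planted among values in random order, and 42 of 42 windows past the bound overlapped it. This does not show how well weaker runs are found, or how often neighbours that move together form a run. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.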

Results

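RNA was sequenced from PC9 cells, an established human lung adenocarcinoma line whose EGFR gene carries an activating mutation, and from PC9 cells in which AXL had been knocked out. AXL is a receptor tyrosine kinase of the TAM family, whose ligand is GAS6. The labels give 7 libraries: 3 of parental PC9, and 4 of AXL knockout cells that come from 2 clones with 2 libraries each. Each clone was grown from a single cell, so the libraries of one clone share that cell's history, and nothing in the labels says that the libraries of a group came from separate cultures. The libraries were made by bulk MARS-seq, which reads tags from the 3' ends of polyadenylated transcripts. The values come from the authors' deposited table, which holds 1 row per gene with the mean normalized count over the libraries, the log2 fold change, its standard error, the Wald statistic, the p-value and the adjusted p-value. It has 16527 rows, of which 16522 carry a test. The mean normalized counts sum to 12209504, the depth of an average library; totals of single libraries were not analysed here. Size factors read from the lowest rows of the table lie between 0.938 and 1.06, so the libraries differed little in the scaling applied to them. Fold changes are knockout over parental and are followed by the authors' standard error. Group levels are normalized counts implied by the mean and the fold change in that table, and they carry no spread between libraries. Levels of single libraries and differences between the clones were not analysed here.

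The comparison of AXL knockout with parental cells addresses what the loss of AXL changes in an EGFR-mutant lung cancer line. The series title ties that question to error-prone DNA replication and drug resistance. The targeted gene had one of the lowest fold changes in the authors' deposited table. AXL (ENSG00000167601; GRCh38 chromosome 19, 41219203 to 41261766) had a log2 fold change of -6.28 ± 0.18, with a 95% interval of -6.64 to -5.92 and an adjusted p of 1.15e-255 from the authors' Wald test. Its implied level was 1417 in parental and 18.2 in knockout cells, 77.6-fold lower. Its ligand GAS6 (chromosome 13, 113820549 to 113864067) fell too, with -5.33 ± 0.35 and levels of 213 and 5.31. PROS1, the other TAM ligand, was barely detected, with 3.35 in parental and 0.175 in knockout cells. The sister receptors did not pass the test, at 0.05 ± 0.08 for TYRO3 and 0.09 ± 0.29 for MERTK.

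Across the transcriptome, 3228 genes were higher and 3053 lower in AXL knockout cells at an adjusted p under 0.05 in the authors' deposited table, 38.0% of the genes tested. Most changes were small. The median absolute log2 fold change of the changed genes was 0.49, and 4780 of the 6281 (76.1%) changed by less than 2-fold. At least 2-fold changes numbered 734 higher and 767 lower, at least 4-fold changes 241 and 349, and at least 16-fold changes 50 and 115. These counts use the fitted fold and include the genes near the floor described below. How much of each class those genes make up was not counted. Precision followed depth, since the median standard error was 0.71 for genes with a mean under 20, 0.19 from 20 to 200, 0.09 from 200 to 1000 and 0.06 above 1000. For 167 of the changed genes, 57 higher and 110 lower, the group with less signal held 3 implied reads or fewer in all. Their fitted fold is therefore not a usable size, and levels are given in its place. The lower level is computed from that same fold, so it marks only a group near the floor and is not a measured value. A t distribution with 5 degrees of freedom in place of the normal one left 1862 higher and 1614 lower genes. That setting, like the authors' standard errors, still counts the 4 knockout libraries as separate samples although they come from 2 clones.

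**Figure D1:**
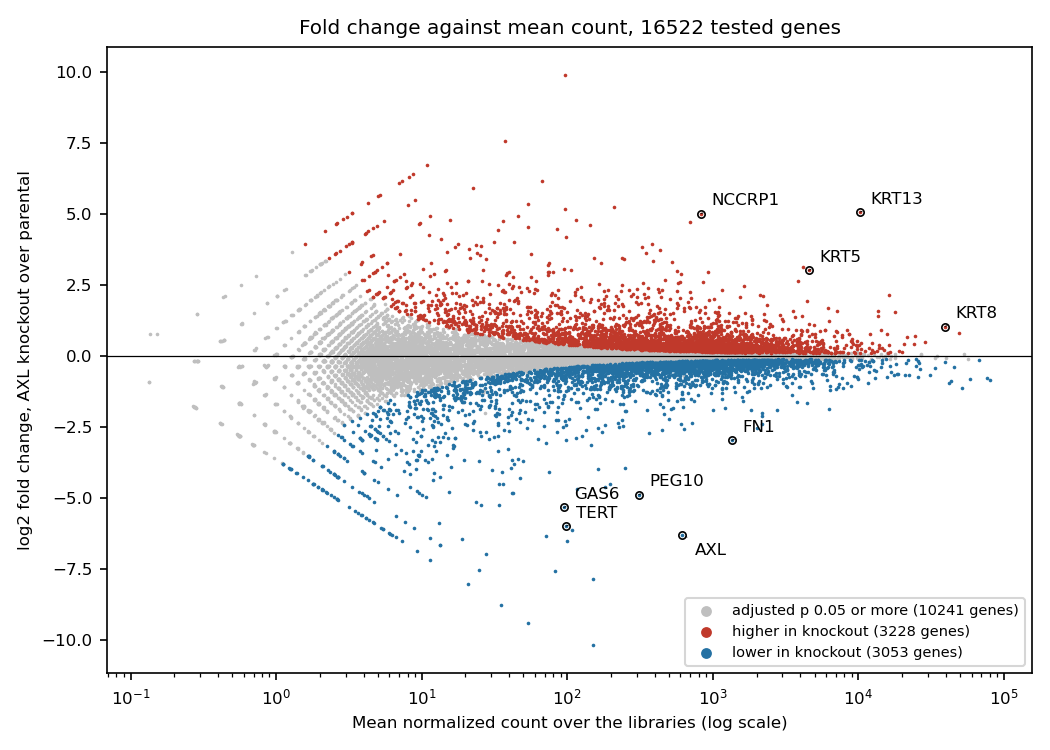
Log2 fold change of AXL knockout over parental PC9 (vertical axis) against the mean normalized count over the libraries (horizontal axis, log scale) for the 16522 tested genes of the authors' deposited table. Each point is a gene, red for the 3228 higher and blue for the 3053 lower at an adjusted p under 0.05; AXL lies at -6.28 and KRT13 at 5.07.

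The 12 largest rises of the authors' deposited table included a pair of keratins. KRT13, a keratin of the layers above the basal cells in mucosal epithelia (chromosome 17, 41500981 to 41505705), went from 523 to 17531, a log2 fold change of 5.07 ± 0.14. Its type II partner KRT4 rose by 5.25 ± 0.63, from 9.45 to 360. ZNF750, a transcription factor of epidermal differentiation, rose by 4.93 ± 0.55 to 79.0, and NCCRP1 by 5.02 ± 0.14, from 43.7 to 1415. Above the floor the largest rise was that of AOC1, an amine oxidase (6.17 ± 0.66), and the others were UNC13A, a synaptic vesicle priming factor (5.34 ± 0.58), PLAAT4 (5.18 ± 0.63) and PRR15L (4.78 ± 0.34). Further rises started from 3 parental reads or fewer. The level of DIO3OS, a non-coding RNA, was 0.179 in parental and 168 in knockout cells. TMPRSS3, a transmembrane serine protease, stood at 0.348 and 65.4, ELFN1-AS1 at 0.648 and 38.7, and EPB41L3 at 0.971 and 26.8. ELFN1-AS1 and DIO3OS are antisense or divergent transcripts, and the sources used here do not say whether the counting used strand.

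Among the falls, BCAT1, the cytosolic branched-chain amino acid transaminase, went from 350 to 1.52 in the authors' deposited table (log2 fold change -7.85 ± 0.60). MSX1, a homeobox transcription factor, went from 190 to 1.01 (-7.55 ± 0.74). The other 10 genes with the lowest fold changes had 3 knockout reads or fewer. CA12, a membrane carbonic anhydrase, had a level of 126 in parental and 0.186 in knockout cells, and C15orf48 had 81.6 and 0.186. ACSS3, a mitochondrial acyl-CoA synthetase, stood at 63.8 and 0.507, and PLAGL1, an imprinted zinc finger gene, at 57.1 and 0.307. DTNA stood at 31.0 and 0.307, NPR3, the natriuretic peptide clearance receptor, at 26.6 and 0.185, and SLITRK5 at 21.4 and 0.184. The remaining 3 lie beside one another in the beta-globin region of chromosome 11. OR51B5 had 353 and 0.308, HBE1, embryonic globin, 48.4 and 0.186, and OR51B4, an olfactory receptor, 30.7 and 0.307. OR51B5 (5303444 to 5505652) and OR51B4 (5301014 to 5301946) both lie within the annotated span of HBE1 (5268345 to 5505652), so which of them the reads belong to is uncertain.

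The authors' statistics were next set against 42 gene lists with limma's competitive set test (cameraPR, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Relative to other genes, 3 lists were higher and 10 were lower at an adjusted p under 0.05. An estimated correlation needs values per library and was not used here. With the log2 fold change in place of the statistic, 2 of these 13 calls held, for the mesenchymal and TAM lists.

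Genes of the mesenchymal state fell in the authors' deposited table. Of 23 measured members, 16 were lower, 1 was higher and 6 did not pass (17 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.13 and a set test adjusted p of 1.8e-17. FN1, which encodes the matrix protein fibronectin (chromosome 2, 215360440 to 215436172), went from 2694 to 344 (-2.97 ± 0.08). SNAI2, a repressor of epithelial genes, fell by 2.66 ± 0.15 on the log2 scale and ITGA5, the fibronectin receptor subunit, by 1.13 ± 0.07. CD44 was the 1 member that rose (0.44 ± 0.04). The mitochondrial list, fixed as a measure of RNA quality, moved in the same comparison, with a median of -0.73. The ribosomal protein list, also fixed for RNA quality, had a median of 0.05. TGF-beta targets overlap with the mesenchymal list and fell likewise, with 11 of 17 lower and 3 higher, a median of -0.41 and an adjusted p of 7.84e-07 (range over all alternatives 1.36e-09 to 0.0998). TGFBI (-1.62 ± 0.05), LTBP2 (-1.91 ± 0.08) and the ligand TGFB2 (-1.37 ± 0.11) were among the members with the smallest p. Of 18 YAP/TEAD targets, 7 were lower and 2 higher (8 and 2 adjusted over the list alone), with a median of -0.15 and an adjusted p of 4.7e-04. AXL itself is in that list, and without it the adjusted p was 0.0708 (range over all alternatives 1.59e-04 to 0.143). The other members with the smallest p were F3, tissue factor (-1.09 ± 0.05), CCN1 (-0.85 ± 0.07) and NT5E (-0.84 ± 0.07). The TAM list, with 3 of 5 lower, none higher and an adjusted p of 2.05e-06, likewise lost its call without AXL (adjusted p 0.145, range over all alternatives 1.09e-11 to 0.167). Its median was -4.26, or -2.16 with PROS1 set to the floor of 3 reads over the knockout libraries.

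Epithelial genes rose as a list in the authors' deposited table, with 20 of 30 members higher, 4 lower, a median of 0.33 and an adjusted p of 1.11e-06 (range over all alternatives 1.07e-06 to 0.165). The simple-epithelium keratins KRT8 and KRT18 went from 24512 to 50455 (1.04 ± 0.04) and from 17826 to 29451 (0.72 ± 0.04). ST14, the protease matriptase, rose by 0.75 ± 0.04, and it lies in a run of higher genes on chromosome 11 whose neighbours had a median of 0.67. LAMA3, a laminin-332 chain of the basement membrane, fell by 2.39 ± 0.08. E-cadherin, CDH1, named here after its value was seen, was slightly lower at -0.33 ± 0.06. The mitochondrial list moved beside this list too, at a median of -0.73, while the ribosomal protein list had 0.05. Squamous and basal genes went both ways, with 5 of 16 higher and 7 lower (5 and 8 adjusted over the list alone), a median of -0.52 and an adjusted p of 0.504 (range over all alternatives 0.00336 to 0.844). KRT5 (3.02 ± 0.20, from 900 to 7283) and KRT15 (2.00 ± 0.08) rose. The integrin ITGA6 (-0.71 ± 0.05) fell. Of 15 lung lineage genes, 8 were higher and 4 lower, with a median of 0.56 and an adjusted p of 0.434 (range over all alternatives 0.0028 to 0.861). ABCA3, the lipid transporter of surfactant-producing cells, rose by 2.16 ± 0.21 and FOXA1 by 0.56 ± 0.06. LPCAT1 (-0.44 ± 0.04) and the mucin MUC5B (-2.14 ± 0.29) fell.

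**Figure D2:**
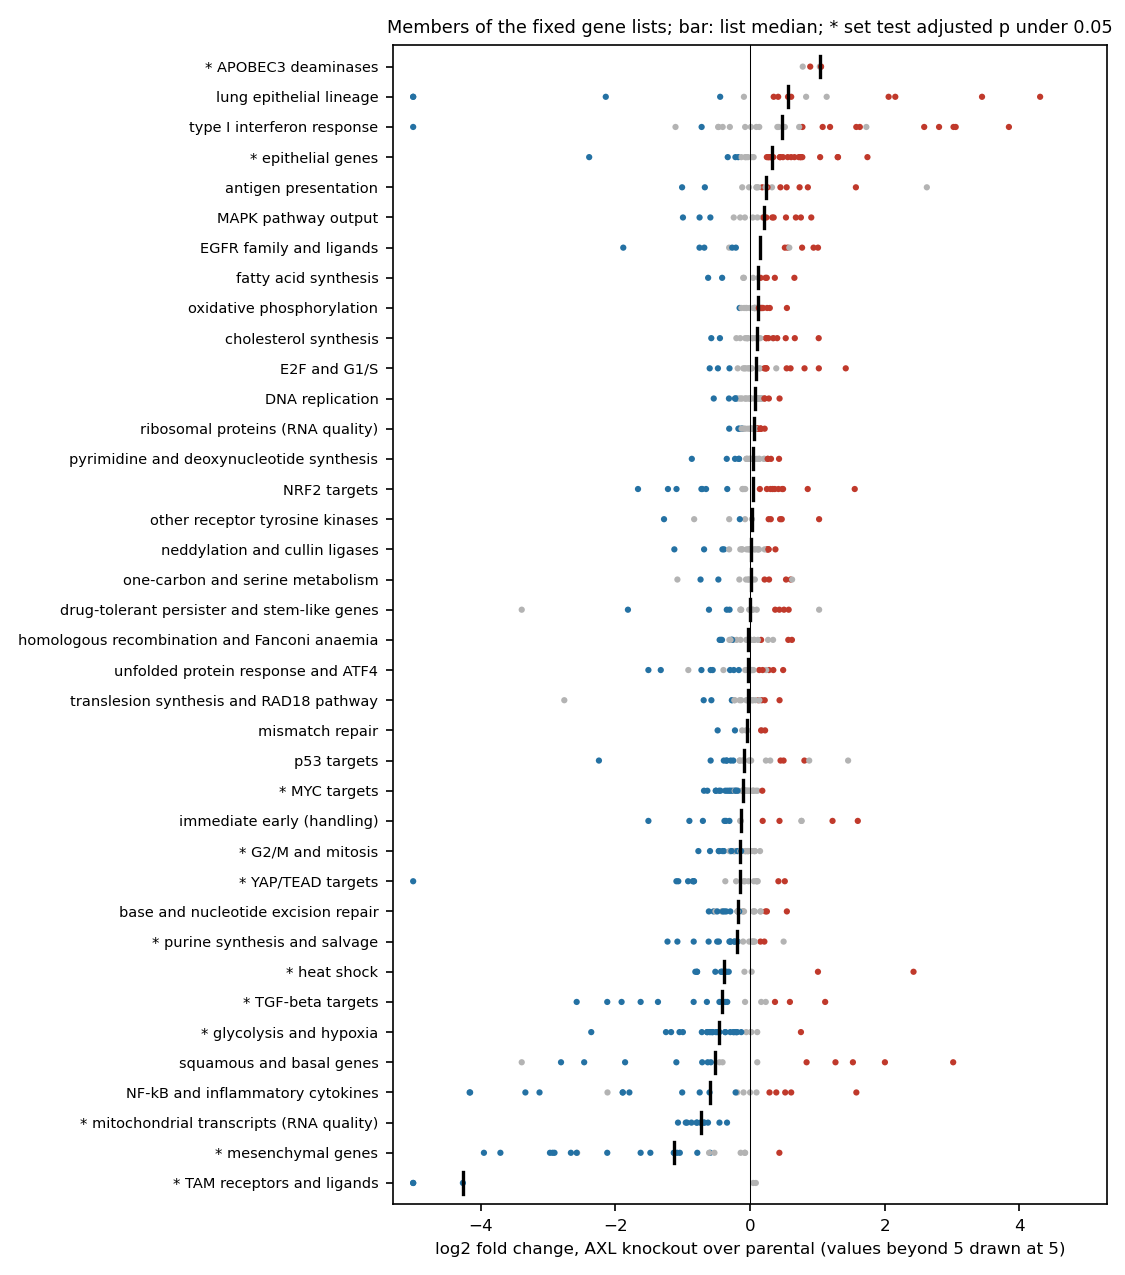
Log2 fold change of AXL knockout over parental PC9 (horizontal axis, values beyond 5 drawn at 5) for the measured members of the fixed gene lists (vertical axis, sorted by median), without the lists of other cell types. Each point is a gene, red if higher and blue if lower at an adjusted p under 0.05, black bars are list medians and asterisks mark lists past the set test; mesenchymal genes have a median of -1.13 and epithelial genes of 0.33.

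Transcripts of the mitochondrial genome, a list fixed as a measure of RNA quality, fell together in the authors' deposited table. All 13 protein-coding members were lower, with a median of -0.73 and a set test adjusted p of 9.63e-22 (range over all alternatives 6.86e-24 to 0.0765). They share the mitochondrial genome, while the set test counts them as separate members. MT-ND6 had -1.07 ± 0.06, MT-ND5 -0.95 ± 0.05, MT-ND1 -0.93 ± 0.05 and MT-CO1 -0.87 ± 0.06. Over the 21 mitochondrial genes tested, 19 were lower and none was higher by the authors' Wald test, and 0 were higher at an unadjusted p under 0.05. The implied share of all counts was 4.07% in parental and 2.34% in knockout cells. Nuclear genes of oxidative phosphorylation did not fall with them, since 12 of 28 were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.12 and an adjusted p of 0.184 (range over all alternatives 0.00665 to 0.861). SDHD (0.55 ± 0.07), in a run of higher genes on chromosome 11, and UQCRH (0.29 ± 0.06) had the smallest p. Glycolysis and hypoxia genes fell, with 24 of 29 lower, 1 higher, a median of -0.45 and an adjusted p of 1.25e-11 (range over all alternatives 1.13e-11 to 0.101). BNIP3, a hypoxia-induced mitophagy receptor, went from 1324 to 259 (-2.36 ± 0.08), CA9 fell by 1.25 ± 0.10, PFKFB3 by 1.00 ± 0.07 and the glycolytic enzyme PGK1 by 0.55 ± 0.04. Heat shock genes fell as well, with 10 of 14 lower and 2 higher, a median of -0.38 and an adjusted p of 1.97e-07 (range over all alternatives 1.84e-07 to 0.965). HSP90AA1, the inducible cytosolic HSP90, went from 77129 to 43959 (-0.81 ± 0.04), BAG3 had -0.79 ± 0.05 within the chromosome 10 run that also holds BNIP3, HSPA1A -0.78 ± 0.06 and HSPH1 -0.51 ± 0.05.

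The lists that follow the series title hold genes of DNA damage tolerance, repair and nucleotide supply. In the authors' deposited table, 4 of 22 genes of translesion synthesis and the RAD18 pathway were higher and 3 lower, with a median of -0.03 and an adjusted p of 0.778. RAD18, the ubiquitin ligase that modifies PCNA at stalled forks, went from 856 to 576 (-0.57 ± 0.07). HLTF, a ligase that extends this mark, fell by 0.69 ± 0.09 within a run of lower genes on chromosome 3, while PCNA rose by 0.44 ± 0.05 and POLD2 by 0.22 ± 0.05. Of 36 DNA replication genes, 4 were higher and 5 lower (median 0.08, adjusted p 0.778). RFC1 (-0.54 ± 0.06) and RPA1 (-0.22 ± 0.05) lie in runs of lower genes, and GINS4 had -0.31 ± 0.08. Mismatch repair had 2 higher and 2 lower of 8 (median -0.05, adjusted p 0.778), with MLH3 at -0.48 ± 0.10 and MSH6 at -0.22 ± 0.05. Homologous recombination and Fanconi genes had 3 higher and 6 lower of 26 (3 and 8 adjusted over the list alone, median -0.02, adjusted p 0.652), with MRE11 at 0.57 ± 0.08 and XRCC2 at -0.43 ± 0.08. Base and nucleotide excision repair had 3 higher and 9 lower of 24 (3 and 10 adjusted over the list alone, median -0.17, adjusted p 0.316, range over all alternatives 0.0361 to 0.965), among them PARP1 at -0.61 ± 0.06, ERCC2 at -0.54 ± 0.08 and the repair polymerase POLB at 0.55 ± 0.12.

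The APOBEC3 cytidine deaminases, which edit single-stranded DNA, rose in the authors' deposited table. APOBEC3C (1.06 ± 0.06, from 1586 to 3295), APOBEC3B (0.89 ± 0.07, from 743 to 1381) and APOBEC3F (1.05 ± 0.14) were higher. APOBEC3H (0.78 ± 0.54) and the remaining member did not pass, and the list had a median of 1.04 and an adjusted p of 6.57e-04 (range over all alternatives 2.65e-04 to 0.0897). These genes are close copies of one another, so reads may be split among them. APOBEC3B, APOBEC3C, APOBEC3F and APOBEC3H also lie close together on chromosome 22 (38982347 to 39104067), while the set test counts them as separate members. Purine synthesis and salvage genes fell, with 13 of 23 lower and 2 higher (14 and 2 adjusted over the list alone), a median of -0.20 and an adjusted p of 0.00111. PPAT, the first enzyme of the pathway (-1.22 ± 0.09, from 567 to 243), and its neighbour PAICS (-1.08 ± 0.05) lie in a run of lower genes on chromosome 4. ATIC, a later enzyme, had -0.46 ± 0.05. Without the genes of all regional runs the adjusted p of the list was 0.0839 (range over all alternatives 0.00131 to 0.861). Pyrimidine and deoxynucleotide synthesis had 4 higher and 5 lower of 27 (3 and 5 adjusted over the list alone, median 0.04, adjusted p 0.891), with UPP1 at -0.86 ± 0.06 and DUT at 0.43 ± 0.06. One-carbon and serine metabolism had 4 higher and 2 lower of 14 (4 and 3 adjusted over the list alone, median 0.01, adjusted p 0.778), with PHGDH at 0.60 ± 0.05 and PSPH at -0.73 ± 0.07. Neddylation and cullin ligase genes had 5 higher and 4 lower of 25 (median 0.01, adjusted p 0.826). DCUN1D4, in the chromosome 4 run, had -1.12 ± 0.12 and CUL4A, in a run on chromosome 13, had -0.41 ± 0.06.

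Within the receptor and signalling lists of the authors' deposited table, 5 of 12 EGFR family genes and ligands were higher and 5 lower, with a median of 0.15 and an adjusted p of 0.376. ERBB3 went from 590 to 1187 (1.01 ± 0.07) and ERBB2 from 697 to 1341 (0.94 ± 0.07). The feedback inhibitor ERRFI1 rose by 0.56 ± 0.05 and the ligand HBEGF fell by 0.75 ± 0.07. EGFR, named after its value was seen, had -0.21 ± 0.06. Of 11 other receptor tyrosine kinases, 5 were higher and 2 lower (median 0.03, adjusted p 0.746), with FGFR1 at -1.28 ± 0.08 and INSR at 1.03 ± 0.17. MAPK output genes had 9 higher and 3 lower of 19 (9 and 4 adjusted over the list alone, median 0.20, adjusted p 0.485, range over all alternatives 0.0369 to 0.863). FOSL1 fell by 0.75 ± 0.05, and the feedback regulator SPRY4 rose by 0.68 ± 0.07. NF-kB and cytokine genes had 5 higher and 11 lower of 21 (5 and 13 adjusted over the list alone, median -0.60, adjusted p 0.434, range over all alternatives 1.12e-04 to 0.911). IL11 went from 294 to 33.7 (-3.12 ± 0.17), TNFAIP3 had -0.75 ± 0.06, and LCN2, a secreted iron-siderophore carrier, went from 3364 to 10053 (1.58 ± 0.05). Type I interferon genes had 10 higher and 2 lower of 26 (median 0.47, adjusted p 0.128), with an adjusted p of 0.0455 on ranks (range over all alternatives 0.0021 to 0.381). OAS1 rose by 3.05 ± 0.24, OAS3 by 1.58 ± 0.15 and MX2 by 3.84 ± 0.67, from low parental levels of 18.5, 71.1 and 1.95. The level of IRF7 was 29.9 in parental and 0.507 in knockout cells. Antigen presentation genes had 7 higher and 2 lower of 17 (median 0.23, adjusted p 0.434, range over all alternatives 0.0455 to 0.657), with the peptide transporter TAP1 at 0.86 ± 0.13 and NLRC5 at -1.01 ± 0.13.

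Proliferation lists moved little in the authors' deposited table. G2/M genes had 12 of 30 lower and none higher, with a median of -0.14 and an adjusted p of 0.0224, which was 0.161 with a preset correlation of 0.05 and 0.119 without the genes of regional runs (range over all alternatives 0.00214 to 0.861). MKI67 (-0.77 ± 0.06) and BUB3 (-0.59 ± 0.06) lie in a run of lower genes on chromosome 10, and BUB1 had -0.41 ± 0.09. MYC targets had 15 of 38 lower and 1 higher, with a median of -0.11 and an adjusted p of 0.00417 that became 0.086 with a correlation of 0.05 (range over all alternatives 3.73e-04 to 0.861). ODC1 had -0.63 ± 0.06 and HSPD1 -0.37 ± 0.04. E2F and G1/S genes had 9 higher and 3 lower of 24 (median 0.08, adjusted p 0.376), with E2F2 at 1.42 ± 0.12, CDKN1B at 0.81 ± 0.08 and CCNE1 at -0.60 ± 0.08. Of 21 p53 targets, 3 were higher and 7 lower (median -0.09, adjusted p 0.414). CDKN1A, the cell cycle inhibitor p21, went from 434 to 91.7 (-2.24 ± 0.13), while SESN1 rose by 0.81 ± 0.15. Drug-tolerant persister and stem-like genes had 4 higher and 4 lower of 18 (4 and 6 adjusted over the list alone, adjusted p 0.434), with ALDH3A1 at -1.81 ± 0.06 and ALDH1A3 at 0.50 ± 0.07.

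The remaining metabolic and stress lists did not pass as lists in the authors' deposited table. NRF2 targets had 10 higher and 7 lower of 22 (11 and 7 adjusted over the list alone, median 0.04, adjusted p 0.778). The aldo-keto reductases moved apart, with AKR1C2 at -1.66 ± 0.05 and AKR1B10 at 1.56 ± 0.05, and NQO1 rose by 0.86 ± 0.06. AKR1C2 has near-identical paralogs, so its reads are uncertain. Cholesterol synthesis had 8 higher and 2 lower of 23 (median 0.11, adjusted p 0.242), with LSS at -0.57 ± 0.14. Fatty acid synthesis had 5 higher and 2 lower of 11 (median 0.13, adjusted p 0.778), with ACSS2 at 0.66 ± 0.10 and FADS2 at -0.62 ± 0.09. Unfolded protein response and ATF4 genes had 5 higher and 8 lower of 24 (median -0.03, adjusted p 0.434), with the cystine transporter SLC7A11 at -0.72 ± 0.07 and XBP1 at 0.28 ± 0.06. The test, the median and the mean did not share a sign for the NRF2, pyrimidine, one-carbon, neddylation, other receptor kinase, immediate early and blood cell lists.

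Lists of other cell types, of RNA quality and of handling were also read in the authors' deposited table. Of the RNA quality lists, the mitochondrial one had the smallest adjusted p of all 42 lists in the set test (9.63e-22, 13 of 13 lower), in the same comparison as the lists above. That test counts the 13 members as nearly independent although they share the mitochondrial genome, so this rank is uncertain. Ribosomal protein genes had 9 higher and 5 lower of 31 (median 0.05, adjusted p 0.777), with RPL32 at -0.31 ± 0.05 and RPS19 at 0.22 ± 0.04. Immediate early genes had 4 higher and 6 lower of 14 (6 and 6 adjusted over the list alone, median -0.14, adjusted p 0.757), with KLF6 at -0.70 ± 0.10 and IER2 at 0.44 ± 0.07. Of 4 endothelial markers measured, 1 was higher (2 higher and 1 lower adjusted over the list alone). The call of that list (adjusted p 0.00109) came with PECAM1, which went from 351 to 1777 (2.34 ± 0.07). On ranks it was lost, with an adjusted p of 0.538 (range over all alternatives 5.83e-05 to 0.538). CDH5 had -0.57 ± 0.25 and ESAM 0.00 ± 0.09, and VWF was near the floor. Blood cell markers had 2 higher and 1 lower of 6 (2 and 2 adjusted over the list alone, median -0.38, adjusted p 0.116, range over all alternatives 0.0272 to 0.965). LCP1 went from 9432 to 4093 (-1.20 ± 0.05), and CD14 rose by 2.57 ± 0.70 to 13.4. Both fibroblast markers measured were lower (adjusted p 0.434, range over all alternatives 0.0017 to 0.588), COL1A1 at -0.59 ± 0.17 and MFAP5 from 3.95 to 0.176. Of 3 neuroendocrine markers, 2 were lower and none higher (1 higher and 2 lower adjusted over the list alone, median -1.07, adjusted p 0.434, range over all alternatives 0.0283 to 0.68), with UCHL1 at -1.07 ± 0.15 in a run of lower genes on chromosome 4 and SCG2 at -1.34 ± 0.40.

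Changed genes also clustered along chromosomes, a result that was looked for after the fold changes had been seen. Fold changes of the authors' deposited table were placed on GRCh38 with GENCODE 29, and medians of 21 neighbouring protein-coding genes were set against 1000 permutations of gene order over 10404 genes. There were 16 runs past the permuted bounds of -0.37 and 0.44, of which 11 were lower and 5 higher, and they held 592 genes (5.69%). The lowest window median was -1.02 after centring, on chromosome 4, and the lowest in any permutation was -0.50. That run reached from 35948221 to 70807315 and held 58 genes with a median of -0.48, of which 43 were lower and 5 higher. Its lowest window ran from FRYL to POLR2B (48497361 to 57031168), with 18 of 21 genes lower and none higher. The highest run, on chromosome 3 (25718944 to 38137242), had 19 of 27 genes higher and 2 lower, with a median of 0.85. Runs of higher genes also lay on chromosome 12 (119667753 to 124882668, 51 of 62 higher, median 0.57) and on chromosome 11 (108472105 to 119018691, 43 of 50 higher, median 0.48, and 122655675 to 130916509, 29 of 41 higher, median 0.56). A run of lower genes on chromosome 17 (799313 to 7312463) had 63 of 81 genes lower and a median of -0.40.

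**Figure D3:**
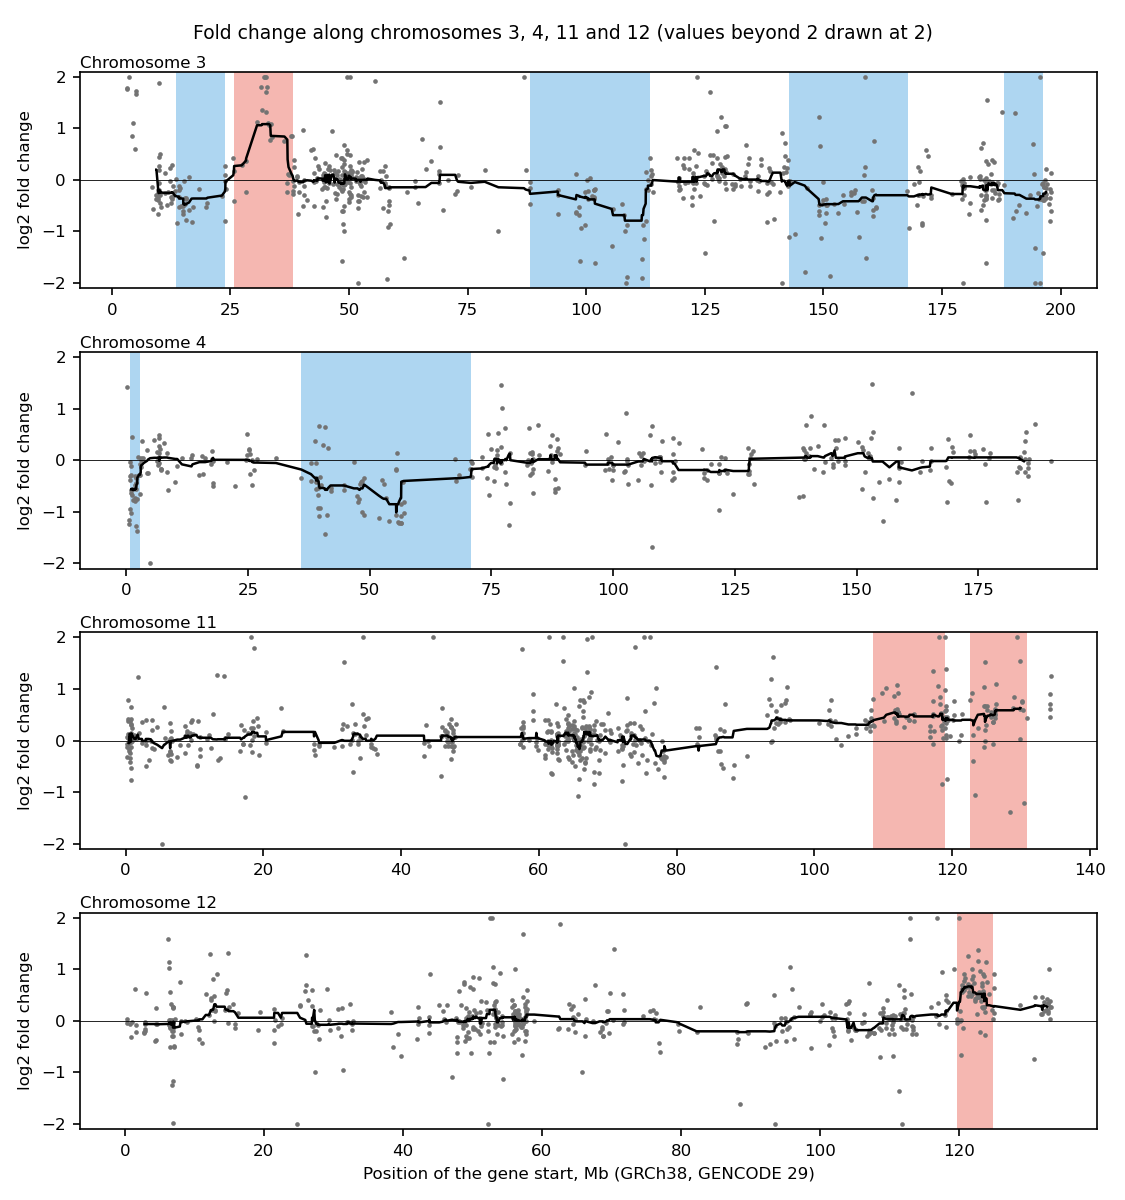
Log2 fold change of AXL knockout over parental PC9 (vertical axis, values beyond 2 drawn at 2) against the position of the gene start in Mb (horizontal axis, GRCh38) for protein-coding genes with a mean of at least 50 on chromosomes 3, 4, 11 and 12. Grey points are genes, the black line is the median of 21 neighbouring genes, and shading marks runs of lower (blue) and higher (red) genes; the shaded chromosome 4 run from 35948221 to 70807315 has a median of -0.48.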

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

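The alternatives with a t distribution, a fold change bound, centring and all those for the lists were chosen after the data were seen. A threshold of 0.01, a mean count of at least 20 and centring kept the counts of higher and lower genes within 1.5 times. The counts of 3228 higher and 3053 lower became 734 and 767 with a 2-fold minimum, 733 and 695 when tested against an absolute log2 fold change of 0.5, and 1862 and 1614 with a t distribution of 5 degrees of freedom. These settings are stricter by construction. AXL stayed past the threshold, with an adjusted p of 5.22e-04 under the t distribution and 2.19e-216 against the bound of 0.5. Of 191 other named genes past the threshold, 179 stayed past it with the t distribution and 111 against the bound of 0.5, and all 180 with a mean of at least 20 did so under that filter. The named genes had been picked from these same data by large fold or small p, so these shares do not stand for all calls. The count of higher lists went from 3 to 5 on ranks, to 6 against random matched lists and to 1 with the log2 fold change in place of the statistic. The count of lower lists went from 10 to 4 with the log2 fold change. These are not the same lists throughout. With the log2 fold change, 2 of the 13 calls held, both of lower lists, and the 1 higher list was that of type I interferon genes (cameraPR adjusted p 0.00837). The cause was not tested. Of the 13 list calls, 13 held with a mean of at least 20, 11 with a correlation of 0.05, 11 against random lists, 11 without AXL, 11 without regional runs and 10 each on ranks and with the t distribution. No list with a call changed direction. No paired analysis was possible because the table analysed holds 1 value per gene and no values per library. For the same reason the other size factors (RLE, upper quartile), edgeR, limma-voom, an unfiltered fit, other pseudocounts, leaving out each library, the 3-group and single-clone models, duplicateCorrelation, fry, an estimated correlation and other splits of the libraries were not run. Depth limits genes with a mean under 20, of which 13.8% passed the test against 59.4% above 1000.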

Other observations

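The tests of gene order, of the held-out genes on chromosome 4, of genes matched on GC content and transcript length and of the mitochondrial transcripts, and the adjusted and run-free values for the purine list, were chosen after the results had been seen, as were the genes of the next paragraph.

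Above the floor, the authors' deposited table has further large changes outside the lists. TERT, the catalytic subunit of telomerase (GRCh38 chromosome 5, 1253147 to 1295069), went from 224 in parental to 3.54 in AXL knockout cells (log2 fold change -5.98 ± 0.42). EYA4, a transcriptional coactivator and phosphatase, went from 231 to 2.53 (-6.51 ± 0.48), GNB4, a G protein beta subunit, from 164 to 2.03 (-6.34 ± 0.53), and EMB from 247 to 3.55 (-6.12 ± 0.41). PEG10, an imprinted gene of retrotransposon origin, went from 692 to 23.6 (-4.88 ± 0.17). The membrane-bound matrix metalloproteinase MMP14 had -4.68 ± 0.26, PDE2A -4.62 ± 0.21 and MUC4, a membrane mucin, -4.49 ± 0.19. On the rising side, S100A8, a calcium-binding protein of inflamed squamous epithelia, went from 45.7 to 1190 (4.70 ± 0.14). WNT11, a secreted ligand, went from 10.1 to 244 (4.60 ± 0.28). VTCN1, an immune checkpoint ligand, rose by 4.19 ± 0.32, BCAS1 by 4.48 ± 0.37, PALMD by 3.96 ± 0.25 and NDRG2 by 3.84 ± 0.17.

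The first pattern is the run of lower genes on chromosome 4, from 35948221 to 70807315. A chance order of changed genes is argued against by the permutations, with p = 0.001, the smallest that 1000 of them can give. They are the permutations by which the run was found, so they are not a further test of it. GC content and transcript length as the cause are argued against as well, but only by how weakly fold changes followed them over all genes. For each of the 58 members, the 20 genes outside all runs nearest in both were taken, and their medians centred on -0.0062 (95% interval -0.032 to 0.027). This comparison replaced the one written beforehand, removal of the trend on both, which left the run at -0.48. That removal is not counted because the trend itself was small (5th to 95th percentile over genes -0.057 to 0.081). With so small a trend the matched genes could hardly be low, so their result restates the small trend and is no separate test. A changed copy number of this segment in the knockout clones is a candidate explanation and stays open: the 22 genes of the segment that had not served to find the run had a median of -0.47, but the interval of -0.72 to -0.05 reaches past the bound of -0.3. By the same bound, reads shared between overlapping genes stay open as a part of the cause. The 16 members that overlap no other annotated gene had a median of -0.40 with an interval of -0.70 to -0.28, just across that bound. This interval lies below the median of 0.01 over all scanned genes, a comparison not set beforehand. Low values in the run were therefore not confined to genes that overlap another. These 16 members helped to find the run, and they say nothing of the cause for members that do overlap. The DNA of the clones was not analysed here, and a regional effect of AXL loss itself was not tested.

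The second pattern is the fall of purine synthesis genes, whose strongest members PPAT and PAICS sit side by side in that run. Their position as the whole cause is argued against, since the other 21 members still ranked lower than other genes by the single test set for it. The cameraPR test of limma gave an unadjusted p of 0.0236, and 11 of them were lower, 2 were higher and their median was -0.19. The evidence is weak, because adjusted over the 42 lists this p is 0.0763 and misses the threshold that the whole list had passed. Leaving out the genes of all runs gave a similar unadjusted p of 0.0246. What lowered the remaining genes was not tested.

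The third pattern is the fall of mitochondrial transcripts. It is relative to nuclear transcripts, since a size factor acts on all genes of a library alike. A joint fall with the nuclear respiratory chain is argued against by the median of 0.12 (0.07 to 0.15) over 28 nuclear genes. RNA degradation, cell handling and extraction that differed between the groups stay open, since libraries of 3' tags hold no measure of RNA integrity. No biological explanation of the fall was tested.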
